A study of Herbaspirillum and Pseudomonas and Pantoea with 8 samples.

How the data were processed

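RNA was sequenced from 4 bacterial strains, Herbaspirillum sp. B12834, Pseudomonas sp. B13192, Pantoea sp. B5559 and Micrococcus sp. B5738. Per the labels' protocols, cells grown in their own media were washed with M9, a defined minimal salts medium, and held for 12 h in M9 with 100 µM FeCl3 or without it. Total RNA was enriched for mRNA and sequenced as paired Illumina reads. Each strain and condition gave 1 library, 8 in all.

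Per the submitters' processing notes, FastQC 0.11.7, Trimmomatic 0.38 and Bowtie2 (version not given) were used. The counting program, its strand setting and its treatment of reads that match several places are not given in the sources used here. The authors deposited 1 table per strain with a read count, an FPKM and a TPM for each gene and library. Per the file headers, the count columns hold reads per gene, and their values were whole numbers. The deposited FPKM values were checked against the counts: they equalled the count over gene length and a library total close to the sum of the counts. FPKM values entered no comparison, and the 8 TPM columns were not used here. The tables listed genes with at least 1 read in both libraries of a strain. A gene read in 1 condition alone is therefore missing from them. The count columns of Herbaspirillum and Pseudomonas are headed M and P, which were read as minus and plus FeCl3 from the library names in the labels. Fold tables by the authors were not used here.

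Positions are those of the deposited tables. For Herbaspirillum, Pseudomonas and Micrococcus they lie on a single contig named for the strain. For Pantoea they lie on a chromosome and 2 plasmids of a reference genome that is not named for the strain. No genome sequence was used here, and gene symbols and products were taken from the tables.

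From the counts, library sizes were scaled with the TMM method of edgeR 4.0.16 under R 4.3.3. Log2 folds (with minus without FeCl3) were computed from CPM values with a prior count of 2. Ribosomal RNA and transfer RNA genes were left out. Genes needed at least 30 reads summed over both libraries, and were called higher or lower at a fold of at least 2. The design has no replicates, so no p-value was computed across genes. Intervals of single genes are 95% Clopper-Pearson intervals of the split of reads between both libraries. They cover counting error only and compare a pair of libraries, not the conditions in general.

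There were 24 gene lists, matched by gene symbol or product wording: siderophore biosynthesis; TonB-dependent receptors; TonB, ExbB and ExbD energy transduction; iron transport (iron and siderophore ABC transport and ferrous iron uptake); heme uptake and degradation; FecI-type sigma factors and FecR anti-sigma factors; iron-responsive regulators; iron storage; iron-sulfur cluster assembly; oxidative stress defence; tricarboxylic acid and glyoxylate cycle; respiratory chain complexes and terminal oxidases; ATP synthase; ribosomal proteins; flagellum and chemotaxis; heat shock proteins and proteases; type VI and type III secretion; exopolysaccharide and alginate; phosphate acquisition; manganese, zinc and other metal uptake; copper and other metal resistance (copper, silver, cobalt-zinc-cadmium and arsenic); sulfate assimilation and sulfonate use; nitrogen assimilation and denitrification; and phage, transposase and mobile elements. A list needed 3 members past the read filter. It was said to stand apart where its median log2 fold lay outside the central 95% of the medians of 10000 random lists of the same size, matched in 10 bins of mean expression. Percentiles describe these libraries and are not p-values. Intervals of list medians are 95% order-statistic intervals over members, or the range where members were few. Random lists and these intervals treat members as independent genes. Members of some lists lie side by side and neighbouring genes can change alike, so both ranges may be too narrow. For lists measured in all 4 strains, the strain medians entered an exact two-sided sign-flip permutation test with Benjamini-Hochberg adjustment.

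Genes were named by a rule. It took the 8 highest and the 8 lowest genes of known product with a mean of at least 50 reads. It added the 4 members that moved furthest in the direction of each list standing apart. It also added the 2 members with the largest change, in either direction, of 7 lists (siderophore biosynthesis, TonB-dependent receptors, iron transport, iron storage, iron-sulfur cluster assembly, iron-responsive regulators and oxidative stress defence). Other genes are named as chosen after their values were seen. The comparisons, lists, naming rule and most alternatives were fixed before the data were examined. Matching by symbol or wording caught some members by chance, such as the acetyl-CoA synthetase gene acsA among siderophore genes. Versions of 17 lists without such members were added after the data were seen.

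Neighbouring genes were pairs on the same strand less than 50 bp apart. Runs were 5 or more consecutive genes past the read filter on one strand, all called in the same direction, and were set against 1000 shuffles of the gene order. Bootstrap intervals used 2000 resamples. Counts of the other strains were thinned at random to the Pantoea reads outside ssrA in 100 draws. The statistics were tested on simulated data with the real genes' means and library sizes, 200 genes changed 3-fold or 8-fold, and counting noise alone. Of the genes changed 3-fold and past the read filter, 98% were recovered for Herbaspirillum (4270 genes in the step), 99.0% for Pseudomonas (5264 genes), 96% for Pantoea (557 genes) and 97% for Micrococcus (2152 genes). Of the genes changed 8-fold, 100% were recovered for each strain.

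Alternatives were DESeq2 1.42.0 size factors, total-count scaling, no read filter or one of 200 reads, prior counts of 0.5 and 10, folds of 1.5 and 4, ribosomal and transfer RNA kept in the library total, ssrA left out of it, and an interval that excludes no change. For lists they were the mean, membership by symbol alone and the versions with chance members removed. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.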

Results

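The comparison asked which genes differ in expression with the iron supply in each of 4 bacterial strains. Herbaspirillum, Pseudomonas and Pantoea are Gram-negative bacteria, and Micrococcus is a Gram-positive actinobacterium. Cells were held for 12 h in minimal medium with 100 µM FeCl3, a ferric iron salt, or without it. Each strain and condition gave 1 library, so no difference has a replicate check, and directions describe a pair of libraries. Without and with FeCl3, the tables held 15193079 and 14494026 reads in genes for Herbaspirillum, 15910697 and 14068680 for Pseudomonas, 13316266 and 11678474 for Pantoea, and 2639983 and 5244834 for Micrococcus.

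A single gene took a large part of the reads in the Gram-negative strains. This was ssrA, which encodes transfer-messenger RNA, a small RNA that frees stalled ribosomes; it was chosen after its values were seen. Its share of gene reads was 20.7% without and 16.6% with FeCl3 in Herbaspirillum, 23.8% and 11.6% in Pseudomonas, and 94.8% and 93.7% in Pantoea. Pantoea was left with 688060 and 736237 reads over all other genes, and its median gene had 18 and 14 reads. Among genes past the read filter, those under 300 bp took 77.2% of the Pantoea reads outside ssrA. The share was 4.46% in Herbaspirillum, 2.46% in Pseudomonas and 3.18% in Micrococcus. The short Pantoea gene rmf alone had 262786 reads without and 231232 with FeCl3, and was chosen after its values were seen. No gene named ssrA was listed for Micrococcus. The tables listed 4412 genes for Herbaspirillum, 5497 for Pseudomonas, 1044 for Pantoea and 2311 for Micrococcus. Of these, 4281, 5269, 553 and 2150 passed the read filter.

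**Figure D1:**
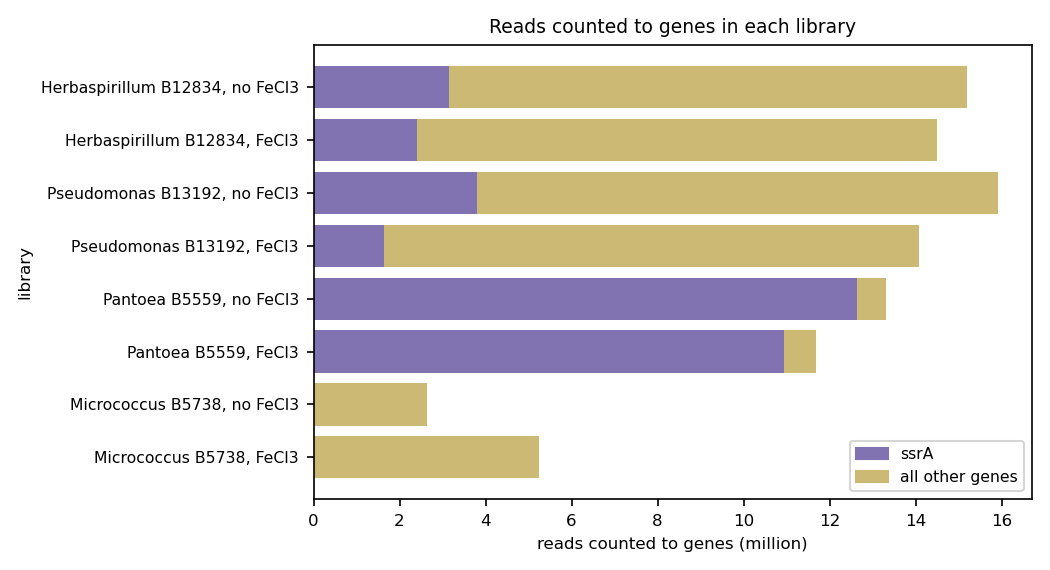
Horizontal bars give the reads counted to genes in each of the 8 libraries, split into ssrA (purple) and all other genes (tan). In both Pantoea libraries ssrA fills over 90% of the bar.

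In Herbaspirillum B12834 genes for siderophores and iron uptake were among the most strongly lowered with FeCl3. The region that holds the siderophore gene pvdA and the receptor gene fhuA was almost silent in the FeCl3 library. That it makes a siderophore, an iron-binding molecule, was inferred from these genes and was not tested. Lists for ribosomal proteins and for copper and other metal resistance stood apart on the higher side, and the highest single genes included mmsA and prpC. At 2-fold, 281 genes were higher and 143 were lower, which was 9.90% of the genes past the filter. Of the called genes, 66.3% were higher. Those of unknown product numbered 84 higher and 78 lower.

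The lowest named genes of Herbaspirillum included genes of siderophore production and uptake. The receptor gene fhuA (FBCC-B12834_1_02898, 3291967 to 3294186 on the strain's contig) fell from 41776 to 74 reads, a log2 fold of −9.07 (counting interval −9.46 to −8.78). Next to it, pvdA (3290555 to 3291874), for the enzyme that hydroxylates ornithine, fell from 6939 to 17 reads (−8.48, −9.42 to −7.96). The peptide synthetase genes lgrB, lgrD_1 and lgrD_2, annotated as linear gramicidin synthase subunits, had log2 folds of −7.91, −6.70 and −6.61. The thioesterase gene pikAV near them had −6.13. Elsewhere on the contig, the receptor gene fiu_2 (−7.64) and the heme gene hemS (−6.50) were among the lowest. All genes from yojI to the last gene past mbtH, 13 genes over 36.8 kb from 3287498 to 3324335, were at least 16-fold lower, with a median log2 fold of −6.70. This region was delimited after its values were seen.

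Lists for iron uptake stood apart in Herbaspirillum, below the random lists. TonB-dependent receptors bring siderophores through the outer membrane. Of 15 genes of that list, 7 were lower and 1 was higher (median log2 fold −0.97, interval −3.66 to −0.02, percentile 0). Without 1 member caught by chance, 7 of 14 were lower. The median was then −1.03 (percentile 0), with an interval of −5.47 to 0.08 that includes 0. Members included fcuA_2 (−5.47) and cirA (−3.66). The receptor that was higher, FBCC-B12834_1_00071, went from 323 to 3461 reads (3.44) and was chosen after its values were seen. Iron transport had a median of −0.32, with 4 of 14 genes lower and 0 higher, among them efeU (−1.85) and futA1 (−1.66); without 4 members caught by chance the median was −0.58 with 3 of 10 lower. Heme uptake and degradation had a median of −0.37, with 2 of 6 genes lower, hemS and pigA (−1.16); 3 of its other members matched by chance, and the median was −1.16 without them. Iron-responsive regulators had a median of −0.85 over 4 genes, with 1 lower. That list held fur (−0.73), the iron-sensing repressor gene, but also the receptor genes fiu_1 (−0.97) and fiu_2 by chance. The gene that was lower was fiu_2, and without both receptors fewer than 3 members were left, so the list was no longer compared.

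Other lists that stood apart on the lower side in Herbaspirillum were heat shock, metal uptake and mobile elements. Heat shock proteins and proteases had a median of −0.38 with 5 of 28 genes lower and 1 higher, including hslV (−1.50), clpS (−1.28) and grpE (−1.21). Manganese, zinc and other metal uptake had a median of −0.34 with 3 of 16 genes lower and 1 higher, with nikC (−1.25) and zntB (−0.89) among its lowest members. The gene mntP (−1.47), for a manganese efflux pump, was a member by chance. Without the 3 such members that list no longer stood apart (−0.19, percentile 7.16). Phage, transposase and mobile elements had a median of −0.43 with 3 of 29 genes lower and 0 higher, and fhuA was one of these by chance wording of its product. Without fhuA the median was also −0.43.

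Lists for ribosomal proteins, iron-sulfur clusters and the citric acid cycle stood apart on the higher side in Herbaspirillum, though most members stayed within 2-fold. Ribosomal proteins had a median of 0.63 (interval 0.43 to 0.85, percentile 100), with 14 of 53 genes higher and 0 lower, such as rplW (1.49), rpsH (1.46) and rplF (1.41). Iron-sulfur cluster assembly had a median of 0.31 with 1 of 14 genes higher, and included fdx_2 (1.01) and hscA (0.83). The tricarboxylic acid and glyoxylate cycle had a median of 0.24 with 2 of 23 genes higher and 2 lower. The glyoxylate gene aceA rose from 612 to 7642 reads (3.67) and the fumarase gene fumA from 3443 to 9022 (1.42). Another fumarase gene, fumC, fell from 5391 to 2062 reads (−1.35) and was chosen after its values were seen. Without the chance members the cycle's median was 0.22 and lay within the random lists. The highest named genes were mmsA (142 to 4534 reads, 5.01, interval 4.79 to 5.28) and mmsB (4.77), of valine breakdown, and prpC (4.09) and prpB (3.69), of propionate breakdown. The others were yfdE (4.05), livH_11 (39 to 642 reads), lptB_10 (3.72) and a citrate lyase gene, FBCC-B12834_1_03278 (4.20).

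Copper and other metal resistance stood apart on the higher side in Herbaspirillum, with a median of 0.29 and 7 of 33 genes higher and 0 lower. Its top members lay side by side: copB rose from 938 to 11091 reads (3.59), and copA_1 (2.99), copC (2.99) and copD (2.61) were also higher. Sulfate assimilation and sulfonate use had a median of 0.30, with 6 of 31 genes higher and 1 lower, such as sir (2.37), cysW (1.82) and tauB_2 (1.73). Exopolysaccharide and alginate had a median of 0.60 over 5 genes, with 1 higher and 1 lower, including bcsZ (1.08) and bcsB (0.90).

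The remaining Herbaspirillum lists lay within the random lists. Siderophore biosynthesis had a median of −0.13 over 3 genes, of which 1 was higher and 1 lower; pvdA was the only member left after chance members were removed. The others were TonB, ExbB and ExbD (−0.47, with exbD_2 at −1.94), ATP synthase (0.42), type VI and type III secretion (−0.49), oxidative stress defence (0.02), respiratory chain (0.01), flagellum and chemotaxis (0.02), phosphate acquisition (0.0026) and nitrogen assimilation (0.07). Too few genes were measured for FecI and FecR, with fecI at −1.51 and fecR at −1.08, and for iron storage, where the bacterioferritin gene bfr stayed within 2-fold (15957 to 9216 reads, −0.76). The genes exbD_2, fecI and fecR were chosen after their values were seen.

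**Figure D2:**
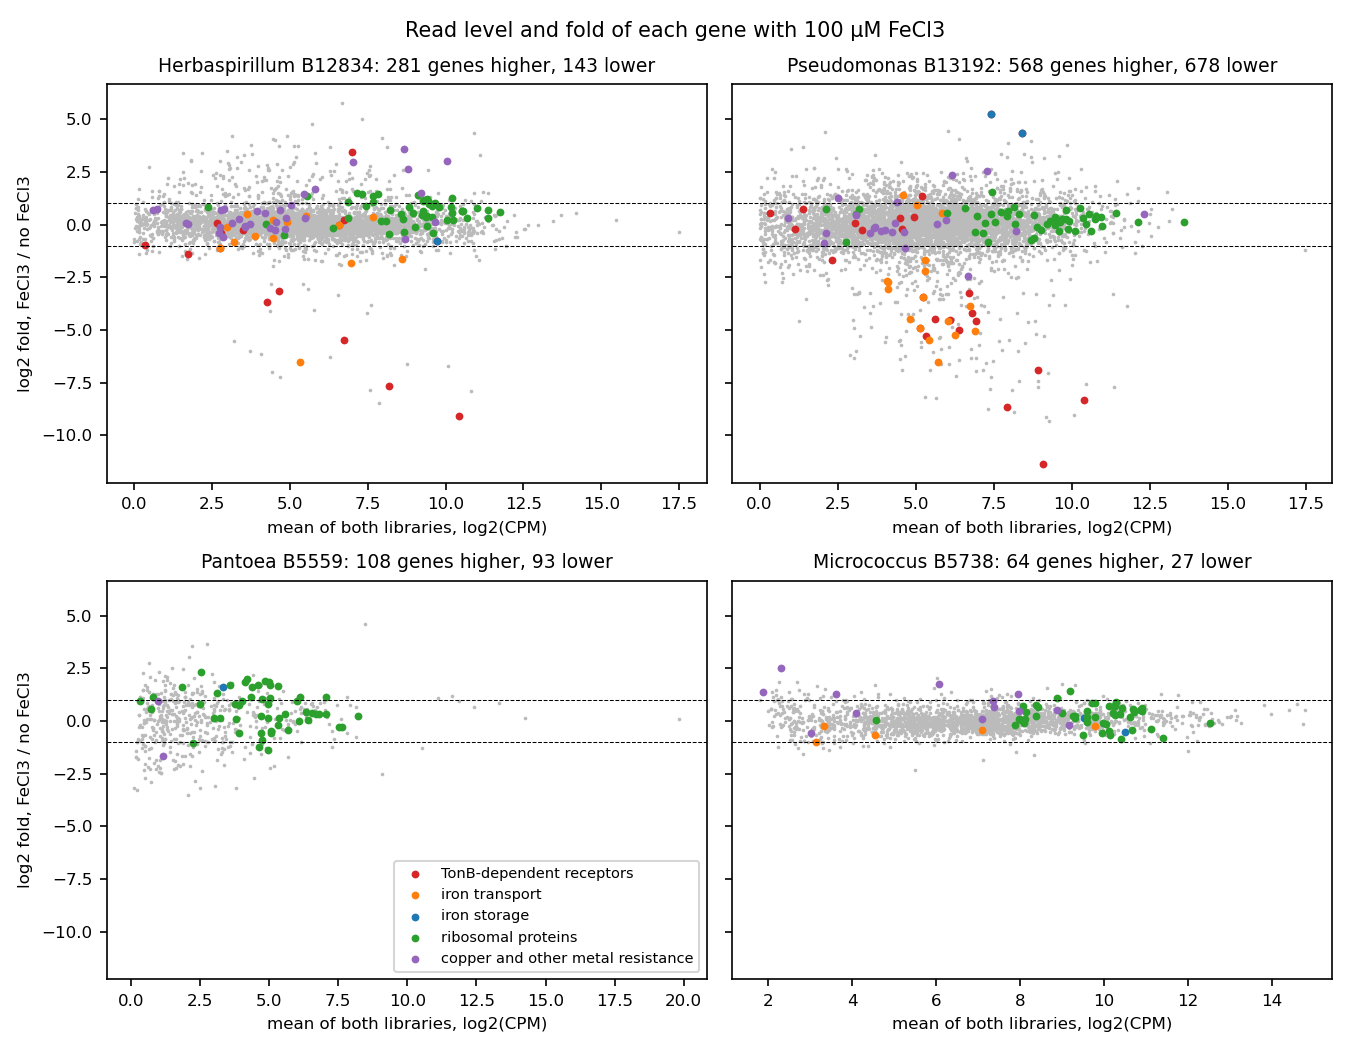
Each point is a gene past the read filter in 1 of the 4 strains, placed by its mean expression (log2 CPM) and its log2 fold with FeCl3, with dashed lines at 2-fold. The lowest point is a TonB-dependent receptor gene (red) in Herbaspirillum (fhuA) and in Pseudomonas (btuB_8), and 2 iron storage genes (blue) lie at the top in Pseudomonas.

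In Pseudomonas B13192 most genes for acquiring iron were lower with FeCl3. They included siderophore synthesis genes, siderophore receptors, the sigma factors that switch such receptors on, and heme and ferrous iron uptake. Genes for storing iron were higher, as were many genes of the respiratory chain, whose enzymes hold iron. At 2-fold, 568 genes were higher and 678 were lower, 23.6% of the genes past the filter. Of the called genes 45.6% were higher, but under scaling by total count this share was 58.2% (754 higher and 541 lower), because that scaling moved the median of all genes by 0.17. Those of unknown product numbered 219 higher and 332 lower.

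Most of the lowest named genes of Pseudomonas were for siderophores or receptors. The receptor gene btuB_8 (FBCC-B13192_1_04307, 4817225 to 4818052 on the strain's contig) fell from 16102 to 4 reads, a log2 fold of −11.38 (−13.84 to −10.61). The siderophore gene pvdA (2147862 to 2149199) fell from 18393 to 27 reads (−9.30, −10.01 to −8.86). The receptor genes cntO_2 (−9.13) and fpvA_2 (−8.65) and a putative receptor gene, FBCC-B13192_1_02207 (−8.32), were nearly as low. So were the fumarase gene fumC_1 (−8.88) and dltA_1 (−9.04), annotated as a carrier protein ligase. The long gene dltA_1 (2098592 to 2111002) lies next to lgrB_1, annotated as a linear gramicidin synthase subunit, so its annotation may not give its role. The hercynine oxygenase gene egtB had 1177 reads without and 2 with FeCl3, a log2 ratio with an interval of −12.24 to −7.34. From 2095170 to 2149199, 18 consecutive genes over 54.0 kb were at least 2-fold lower and 17 of them at least 16-fold, with a median log2 fold of −6.76. This stretch held dltA_1, egtB, fpvA_1 (−6.92) and pvdA, and was delimited after its values were seen.

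**Figure D3:**
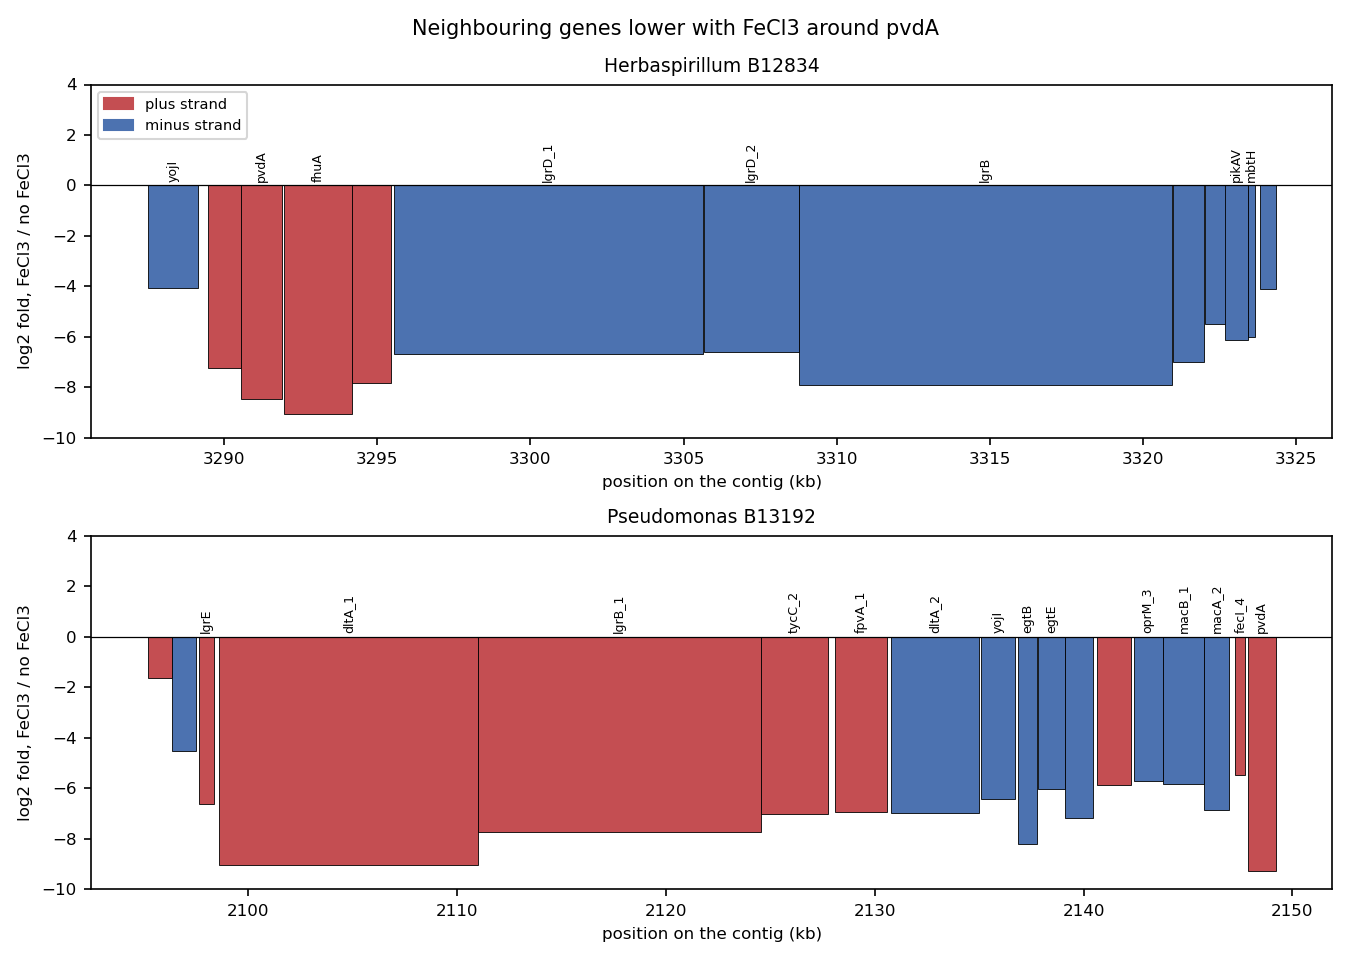
Bars span each gene's start to end (kb) in the regions that hold pvdA in Herbaspirillum (13 genes) and Pseudomonas (18 genes). Height gives the log2 fold with FeCl3 and colour gives the strand. All bars point down, to −9.07 for fhuA in Herbaspirillum and −9.30 for pvdA in Pseudomonas.

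Lists for iron acquisition stood apart far below the random lists in Pseudomonas. TonB-dependent receptors had a median of −3.23 (interval −4.56 to 0.08, percentile 0), with 14 of 25 genes lower and 3 higher; the bacterioferritin genes bfr_1 and bfr_2 were among the higher ones by chance. Iron transport had a median of −3.46 (−4.90 to −2.18), with 14 of 17 genes lower and 1 higher; without 4 members caught by chance the median was −3.89, with 12 of 13 lower and 0 higher. It included efeU (−5.45), efeB (−5.25) and an iron-binding protein gene, FBCC-B13192_1_05598 (−6.51). FecI and FecR genes, for the sigma factors and anti-sigma factors of siderophore receptors, had a median of −3.69, with 15 of 19 lower and 0 higher. Their lowest members were fecR_2 (−6.38) and fecR_6 (−6.22), and fecI_2 had 221 and 1 reads, with an interval of −13.09 to −5.29. Heme uptake and degradation had a median of −2.18, with 5 of 9 genes lower and 1 higher, among them pigA (14341 to 66 reads, −7.71), hmuV (−3.05) and hmuU_1 (−2.69). The other 4 members, among them the higher one, were histidine breakdown genes caught by chance; without them 5 of 5 were lower, with a median of −2.69. Several fecI, fecR and fhuA copies share names, and reads shared between copies cannot be ruled out.

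Lists for the uptake of other metals and for motility also stood apart on the lower side in Pseudomonas. Manganese, zinc and other metal uptake had a median of −0.93, with 10 of 20 genes lower and 1 higher, including mntC (−5.54), zupT_1 (−4.50), ssaB (−4.20) and znuB_2 (−3.87); without 2 members caught by chance its median was −1.45. Flagellum and chemotaxis had a median of −0.37, with 6 of 64 genes lower, 3 higher and 55 within 2-fold. Lower members included flgE (46034 to 18282 reads, −1.32) and cheB_3 (−1.35). Phage and mobile elements had a median of −0.82 with 4 of 9 genes lower, but those 4 were fhuA_1 (−4.19), fhuA_2 (−4.52), fhuA_3 (−4.50) and fhuA_4 (−4.56), receptor genes caught by chance. Without them the median was −0.42 and within the random lists.

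Both iron storage genes of Pseudomonas were higher, and lists of iron enzymes stood apart on the higher side. The bacterioferritin gene bfr_1 rose from 133 to 5002 reads (5.22, interval 4.99 to 5.50) and bfr_2 from 475 to 9595 (4.34). Superoxide dismutase genes went opposite ways, with sodB_1 falling from 4989 to 20 reads (−7.82) and sodB_2 rising from 1458 to 11237 (2.95). Fumarase genes did so too, with fumC_1 falling from 8539 to 16 reads (−8.88) and fumA rising from 4430 to 15814 (1.84). The respiratory chain had a median of 1.20 (interval 0.64 to 1.64, percentile 100), with 19 of 35 genes higher and 1 lower, including ccoN1_2 (3.77), ccoP1 (3.14), nuoK (2.23) and petB (2.15). The tricarboxylic acid and glyoxylate cycle had a median of 0.62, with 9 of 25 genes higher and 2 lower, including sdhD (1.64) and sdhA (1.40). Iron-sulfur cluster assembly had a median of 0.50, with 5 of 17 genes higher and 0 lower, such as hscA (1.71) and fdx_1 (1.46).

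Lists for heat shock and alginate also stood apart on the higher side in Pseudomonas. Heat shock proteins and proteases had a median of 0.81, with 14 of 33 genes higher and 1 lower, led by hslV (749 to 11732 reads, 3.97), groS (2.53) and grpE (2.45). Exopolysaccharide and alginate had a median of 0.60, with 5 of 19 genes higher and 1 lower, including algG (2.12) and algD (1.93); algE had 3 and 57 reads, with an interval of 2.64 to 6.58. The other highest named genes were mtnB_2 (4 to 124 reads, 4.40), ygaZ (3.35), paoA (3.30) and aidB (3.19).

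The remaining Pseudomonas lists lay within the random lists. Siderophore biosynthesis had a median of −0.17, with 2 of 7 genes lower, pvdA and pvdQ (−4.58); the 4 members left after chance members were removed had a median of −2.37, below the random lists. Iron-responsive regulators had a median of 0.48, with iscR_1 (0.48) and iscR_2 (0.87). Of 3 TonB, ExbB and ExbD genes 1 was lower, exbD_5 (−6.63), which was chosen after its values were seen. Ribosomal proteins had a median of 0.26 and ATP synthase of 0.06. Medians were slightly below 0 for oxidative stress defence (−0.02), type VI and type III secretion (−0.13), phosphate acquisition (−0.07), copper and other metal resistance (−0.15), sulfate assimilation (−0.07) and nitrogen assimilation (−0.14). These 6 medians were above 0 under total-count scaling.

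**Figure D4:**
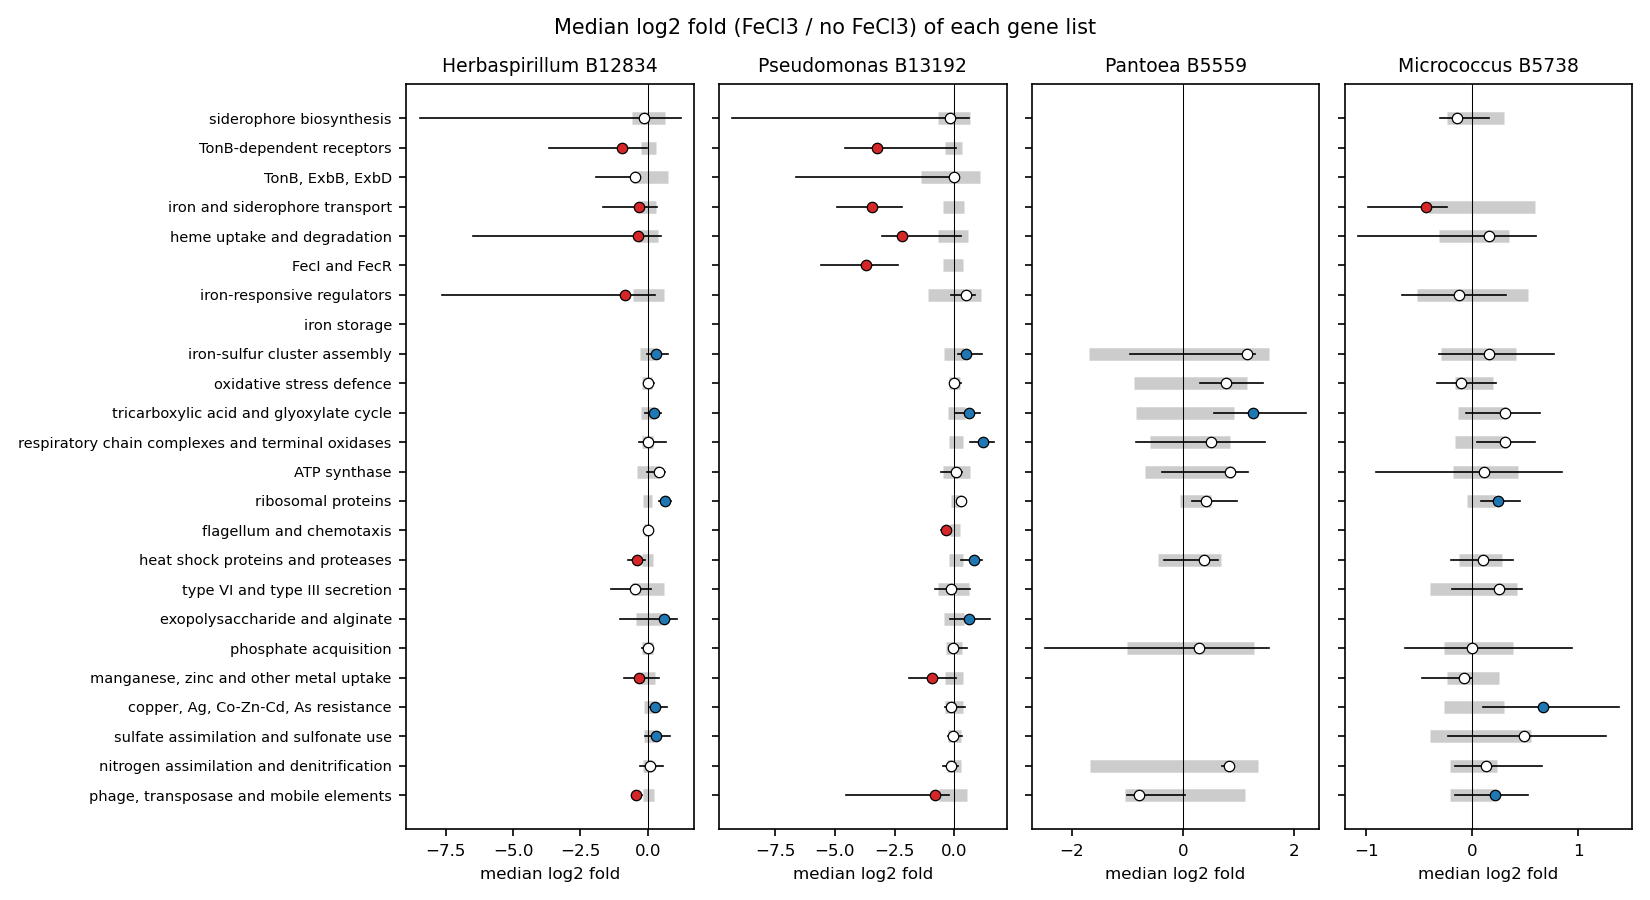
Points are median log2 folds of each gene list in each strain, with black lines for the interval of the median and grey bars for the central 95% of random-list medians; the horizontal axes differ between strains. Red points lie below and blue points above the random lists, and 7 lists are red in Herbaspirillum and 7 in Pseudomonas.

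In Pantoea B5559 no gene of siderophore synthesis, TonB-dependent uptake, iron transport or heme uptake passed the read filter, so iron acquisition could not be compared. Of 9 genes of the citric acid cycle list 5 were higher with FeCl3, as was a gene for the iron-storage protein ferritin. At 2-fold, 108 genes were higher and 93 were lower, 36.3% of the genes past the filter. The share of called genes that were higher was 53.7%, against 44.7% under total-count scaling (89 higher and 110 lower) and 43.8% under DESeq2 scaling (88 and 113). Those scalings moved the median of all genes, which was 0.14 with TMM, by −0.13 and −0.14. Those of unknown product numbered 1 higher and 5 lower.

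Central metabolism was the only list to stand apart in Pantoea. The tricarboxylic acid and glyoxylate cycle had a median of 1.27 (interval 0.57 to 2.22, percentile 99.75), and 1.13 above the median of all genes. Of 9 genes 5 were higher and 0 lower. They included sucC from 8 to 96 reads (3.58, interval 2.87 to 5.16), odhB from 36 to 141 (2.22), mdh from 12 to 46 (2.07) and sucA from 168 to 426 (1.65). One member, the 2-isopropylmalate synthase gene leuA, was caught by chance. Without leuA 5 of 8 were higher, and the median was 1.46 (percentile 99.84), with an interval of −0.96 to 3.58 that includes 0. By their gene numbers sucC, odhB and sucA lie side by side, so they are not independent. The ferritin gene ftnA rose from 67 to 169 reads (1.62, 1.24 to 2.08). The repressor gene fur rose from 13 to 28 reads (1.29), and mntR stayed within 2-fold (0.23). The iron-sulfur genes sufB (1.30) and sufA (1.15) were higher, while the third member of that list, erpA, stayed within 2-fold (50 to 20 reads, −0.94) and was chosen after its values were seen. In the oxidative stress list OsmC (1.15) was higher, as was xseA (1.45), an exodeoxyribonuclease gene caught by chance.

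The most changed named gene of Pantoea encodes a cold shock protein. This cspE gene (I6L77_RS20695) rose from 396 to 7660 reads (4.59, interval 4.45 to 4.74), and other cspE copies share its name, so reads shared between copies cannot be ruled out. Also higher were hisG (3.64), rplW (2.34), fadL (2.18), ilvL (2.06) and rpsJ (1.98). The lowest were a metallopeptidase gene (I6L77_RS11945, 109 to 6 reads, −3.52), seqA (−3.19), udk (353 to 30 reads, −3.16), a transporter gene (I6L77_RS11420, −2.85), dnaE (−2.71), hofQ (−2.38) and clpX (−2.25). The 6S RNA gene ssrS, a regulator of RNA polymerase, fell from 12961 to 1803 reads (−2.53, −2.60 to −2.45).

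The remaining Pantoea lists lay within the random lists. Medians were 0.41 for ribosomal proteins (18 of 53 genes higher and 3 lower), 0.86 for ATP synthase, 0.51 for the respiratory chain, 1.15 for iron-sulfur cluster assembly, 0.77 for oxidative stress defence, 0.84 for nitrogen assimilation, 0.39 for heat shock, 0.30 for phosphate acquisition and −0.79 for mobile elements. Without members caught by chance the medians were 0.13 for the respiratory chain, 0.46 for oxidative stress defence and 0.07 for heat shock, where 8 of 16 genes lay above 0 and 8 below. Flagellum, secretion, metal uptake, copper resistance, iron-responsive regulators and iron storage had fewer than 3 measured genes, and FecI and FecR, exopolysaccharide and sulfate assimilation had 0.

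In Micrococcus B5738 few genes changed. None of the 5 iron transport genes reached 2-fold, and the list's place below the random lists was borderline. The list for resistance to copper and other metals stood apart on the higher side. At 2-fold, 64 genes were higher and 27 were lower, 4.23% of the genes past the filter. Of the called genes 70.3% were higher, but under scaling by total count this share was 46.2% (43 higher and 50 lower), because that scaling moved the median of all genes by −0.12. Those of unknown product numbered 38 higher and 19 lower.

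Iron transport was the only list below the random lists in Micrococcus. It had a median of −0.43 over 5 genes (range −0.99 to −0.24) at percentile 2.15, and a second draw of random lists put it at percentile 2.83, so this call was borderline. Its members included feuB (33 to 29 reads, −0.99, interval −1.82 to −0.29), yusV (−0.66), hbpA (−0.43) and fbpA (−0.25). The siderophore gene iucC went from 105 to 109 reads in libraries of different depth (−0.80, −1.21 to −0.41), and pchA, a hydroxybenzaldehyde dehydrogenase gene caught by chance, had a log2 fold of 0.47. The ferritin gene ftnA (−0.53) and dps (0.15) stayed within 2-fold. The heme-degrading enzyme gene mhuD was the lowest named gene (−1.08, −1.23 to −0.94). It was followed by liaR_2 (−1.04), pup (−1.03), rbpA (−1.03), cmk (−1.01), dinB1 (−0.96), atpC (−0.91) and secE (−0.89).

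Copper and other metal resistance stood apart on the higher side in Micrococcus, with a median of 0.67 (interval 0.11 to 1.39, percentile 99.97) and 5 of 13 genes higher and 0 lower. Its members included the copper sensor gene cueR (84 to 528 reads, 1.77, interval 1.45 to 2.14) and the copper pump gene actP (5 to 28 reads, 1.39). Not all copper genes were higher. The copper exporter genes copA (1712 and 2705 reads, −0.20, interval −0.29 to −0.12) and copB (0.49) stayed within 2-fold, and were chosen after their values were seen. The arsenate reductase gene arsC1 had 3 and 44 reads, with an interval of 1.37 to 5.34. Ribosomal proteins had a median of 0.25 with 2 of 48 genes higher, rpmI (1.42) and rpsJ (1.11). Phage, transposase and mobile elements had a median of 0.22 with 2 of 32 genes higher and 1 lower. Other high named genes were rbn (1.69), mmcO (1.30), merA_3 (1.28), paaB (1.28), cspA (1.28) and sir (1.27). The catalase gene katA stayed within 2-fold (0.88).

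The remaining Micrococcus lists lay within the random lists. Medians below 0 were those of siderophore biosynthesis (−0.14, or −0.28 for the 4 members left after chance members were removed), iron-responsive regulators (−0.12), oxidative stress defence (−0.11) and metal uptake (−0.08). Medians above 0 were those of iron-sulfur cluster assembly (0.16), the tricarboxylic acid cycle (0.31), the respiratory chain (0.32), ATP synthase (0.11), heat shock (0.11), sulfate assimilation (0.49), nitrogen assimilation (0.13) and phosphate acquisition (0.0009). ATP synthase, heat shock and phosphate acquisition were below 0 under total-count scaling. The heme list had a median of 0.16, but 5 of its 6 members were histidine breakdown genes caught by chance, and the other was mhuD. All 5 members of the secretion list (0.25) were caught by chance. TonB-dependent receptors, TonB with ExbB and ExbD, and FecI with FecR had 0 members; iron storage, flagellum and exopolysaccharide had fewer than 3.

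Across the 4 strains, 5 lists for iron enzymes, energy supply and translation had medians of the same sign. Iron-sulfur cluster assembly, the tricarboxylic acid cycle, the respiratory chain, ATP synthase and ribosomal proteins had medians above 0 in 4 of 4 strains. Their means over strains were 0.53, 0.61, 0.51, 0.36 and 0.39. The exact two-sided sign-flip permutation test counted 2 of 16 sign patterns as large for each of these, the fewest that 4 strains allow, with an adjusted p of 0.25 over 10 lists. The design could therefore not reach the 5% level. ATP synthase in Micrococcus was below 0 under total-count scaling. ATP synthase lay within the random lists in each strain, and the respiratory chain stood apart in Pseudomonas alone. For ribosomal proteins, random-list medians ran from −0.05 to 0.52 in Pantoea and from −0.18 to 0.14 in Herbaspirillum. A median above 0 alone therefore does not set a list apart. Iron-sulfur cluster assembly was measured over 3 genes in Pantoea (−0.94 to 1.30), and in Micrococcus 3 of its genes lay above 0 and 3 below. That list lay within the random lists in both of these strains. The respiratory chain median of Herbaspirillum was 0.01, with 15 genes above 0 and 15 below. That of Pantoea was 0.13 without members caught by chance, no higher than the median of all its genes past the filter (0.14). Heat shock (mean 0.23) and nitrogen assimilation (0.23) were above 0 in 3 strains, with exact permutation p of 0.375 and 0.5, adjusted 0.536 and 0.625. Without members caught by chance the heat shock mean was 0.15, with an exact permutation p of 0.625. Heat shock in Micrococcus was below 0 under total-count scaling. Phosphate acquisition (0.06) was above 0 in 3 strains, but by 0.0026 in Herbaspirillum and 0.0009 in Micrococcus. Those medians were −0.0034 under DESeq2 scaling and −0.12 under total-count scaling, and the Pseudomonas one was 0.10 under total-count scaling. Oxidative stress defence (0.17) was above 0 in 2 strains. Exact permutation p for phosphate acquisition and oxidative stress defence were 0.625 and 0.75, adjusted 0.694 and 0.75. Mobile elements had a mean of −0.46 and were above 0 in 1 strain, with an exact permutation p of 0.25, adjusted 0.417.

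Neighbouring genes on the same strand changed alike in Herbaspirillum and Pseudomonas. Across 1309 pairs of neighbouring genes in Herbaspirillum, the log2 folds had a Pearson r of 0.88 (bootstrap interval 0.84 to 0.91), and across 1683 pairs in Pseudomonas r was 0.89 (0.86 to 0.90). In Pantoea r was 0.44 over 88 pairs (0.27 to 0.62), and in Micrococcus 0.25 over 743 pairs (0.18 to 0.32). These correlations run across genes, which are not independent replicates, and 8 were computed over 4 strains and 2 read depths. Random lists drew genes singly, so a list whose members lie side by side could stand apart more readily.

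**Figure D5:**
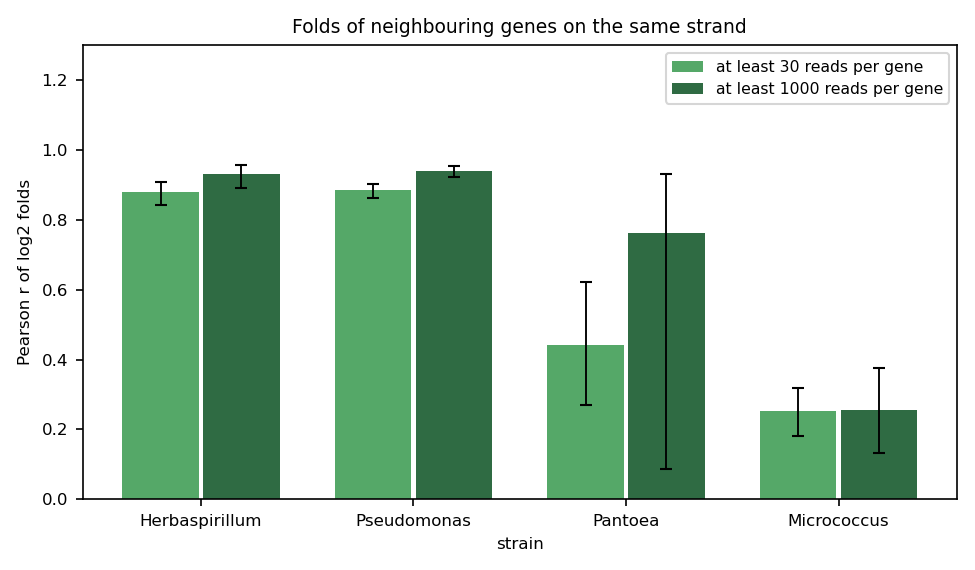
Bars give the Pearson r of log2 folds of neighbouring genes on the same strand in each strain, at 2 read depths, with bootstrap 95% intervals as error bars. Bars of Micrococcus stay near 0.25 at both depths, below those of Herbaspirillum and Pseudomonas.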

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

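The tests of the Pantoea libraries below were all chosen after the result was seen.

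Heat shock genes differed in direction between a pair of strains. Their median log2 fold was −0.38 in Herbaspirillum and 0.81 in Pseudomonas. The genes hslV, hslU and grpE were lower in the former (−1.50, −1.19 and −1.21) and higher in the latter (3.97, 2.23 and 2.45). The list drew attention because it stood apart on opposite sides of the random lists. The difference between the strains was not tested.

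Phage, transposase and mobile element genes also stood apart on opposite sides. Their median was −0.43 in Herbaspirillum, −0.82 in Pseudomonas and 0.22 in Micrococcus. In Pseudomonas the value rested on 4 fhuA receptor genes caught by chance, and it was −0.42 without them. In Herbaspirillum the lower members besides fhuA were 2 transposase genes (−1.29 and −1.04), one of them with 38 and 14 reads. These differences between strains were not tested.

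Ribosomal and transfer RNA genes lay outside the comparisons but held reads. With FeCl3, ribosomal RNA genes had 189.6 CPM in Herbaspirillum (129.3 without), 33.1 in Pseudomonas (17.9 without) and 6.25 in Pantoea (0.451 without, 6 reads against 73). Transfer RNA genes had 1738 CPM in Pseudomonas, against 1387 without FeCl3, but were lower with FeCl3 in Herbaspirillum (1464 against 1602), Pantoea (21.2 against 34.5) and Micrococcus (789.3 against 956.7). Enrichment for mRNA removes ribosomal RNA, and the efficiency of that step was not measured.

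The Pantoea tables listed 1044 genes, fewer than those of any other strain. A lower total of reads outside ssrA is argued against as the whole cause. Each other strain was thinned at random to the 688060 and 736237 Pantoea reads outside ssrA. Each still listed at least 2206 genes in each of 100 draws, against 1043 in Pantoea. The draws kept each strain's own spread of reads over genes. In Pantoea the 10 most read genes, ssrA among them, took 98.96% of gene reads without and 98.92% with FeCl3. The reads left for its other genes were therefore not matched, and too few reads for those genes stays open. An otherwise even library that lost reads to ssrA alone is also argued against. Among the other genes past the read filter, reads fell with gene length (Spearman rho −0.28, −0.36 to −0.20, across genes) where they rose in the other 3 strains. Short transcripts may have been favoured over long ones, for instance through degraded or size-selected RNA. Genes under 300 bp were 12.1% of the genes past the read filter and took 77.2% of the reads outside ssrA. Their share was 4.46% in Herbaspirillum, 2.46% in Pseudomonas and 3.18% in Micrococcus. Much of the Pantoea share lay in a few genes, named after their values were seen, such as rmf (262786 reads without and 231232 with FeCl3) and a cspE copy (100046 and 147210). The share alone therefore cannot tell a few abundant transcripts from short transcripts in general. What might have favoured short transcripts, the match of the strain to its reference genome and a biological difference of this strain all stay open, as these were not tested.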

How the results depend on the processing

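The alternatives that left ssrA out of the library total, removed chance list members, or recomputed the means across strains were tests chosen after the results were seen. No paired analysis was possible within a strain because each condition had 1 library; across strains, the sign-flip test paired the conditions. No named gene, list that stood apart or mean across strains reversed its direction under the alternatives run.

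Counts of called genes stayed within 1.5 times the reported count in 61 of 86 recomputations and moved further in 25. A fold of 1.5 gave 593 higher and 422 lower genes in Herbaspirillum, 1147 and 1216 in Pseudomonas, 194 and 144 in Pantoea, and 223 and 153 in Micrococcus. A fold of 4 gave 101 and 26, 112 and 238, 16 and 31, and 2 and 1. These follow from the threshold itself. Without a read filter Pantoea had 176 higher and 171 lower genes, and with at least 200 reads 35 and 31, because the filter sets how many genes are counted. In Micrococcus at least 200 reads left 36 higher and 12 lower genes. Its lower genes numbered 50 under total-count scaling, which moved the median of all genes by −0.12, and 44 without a filter, which counts more genes. They numbered 17 with a prior count of 10; the cause was not tested.

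Medians of lists that stood apart stayed within their intervals in 206 of 209 recomputations. The 3 exceptions were mobile elements in Herbaspirillum, at −0.67 as a mean and −0.16 with members by symbol alone, and in Micrococcus, at 0.63 with at least 200 reads. The mean rested on the receptor gene fhuA, a chance member, and was −0.37 without it. The cause was not tested for the other values. These recomputations asked whether a value stayed within the interval over members, not whether the list still stood apart. Without members caught by chance, 3 lists no longer did. They were metal uptake (percentile 7.16) and the citric acid cycle (97) in Herbaspirillum and mobile elements in Pseudomonas (14.4). Iron-responsive regulators of Herbaspirillum were left with too few members to compare.

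Log2 folds of named genes stayed within their counting intervals in 519 of 570 recomputations. The other 51 moved in size, 36 of them under total-count scaling, 13 with a prior count of 10 and 2 under DESeq2 scaling. Means over the 4 strains kept their sign in 30 of 30. Reads per gene were fewest in Pantoea, with a median of 18 and 14.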

Other observations

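All tests described here were chosen after the results were seen, the bounds used for the copper genes were changed after their values were seen, and the genes named were chosen after their values were seen.

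Changed genes of Pseudomonas formed long runs along the contig. A run of 11 genes from nuoC to nuoN (3974303 to 3988070) encodes the respiratory NADH dehydrogenase and had a median log2 fold of 1.65. Runs from ccmA onward (9 genes, among them ccm genes of cytochrome c assembly, median 1.68) and from sdhC to lpdG (7 genes of the citric acid cycle, 1.25) were also higher. A run with fumC_1, sodB_1 and zupT_1 had a median of −7.82, and one with folE2, mntC and pyrC_2 had −5.43. The run from kdgR_2 to ghrB_2, with a sugar acid kinase gene, had −5.94. The peptide synthetase genes tycC_3 and grsB_1 lay with dltA_3 in a run with a median of −3.26.

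Runs of Herbaspirillum included transport and resistance genes. An 11-gene run from puuC to meh (3727998 to 3739820) had a median of 3.22, and a run with livH_11 and lptB_10 had 3.40. Genes of an efflux system, mdtA_3, mdtB_1, mdtC and oprM_5, lay in a run with a median of 2.78. A run with the secretion gene hcp1 had −1.57, and one with cydA_1, for an oxidase subunit, had −1.60. In Pantoea the only run held 8 ribosomal protein genes from rplW to rpsQ, with a median of 1.70.

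The hypothesis that operons change as units was tested by counting runs of at least 5 genes. Herbaspirillum had 15 runs, against at most 1 in 1000 shuffles of its gene order, and Pseudomonas had 30, against at most 2. Pantoea had 1 run, against a mean of 0.047 and at most 2 in its shuffles, and 46 of its 1000 shuffles had at least 1. Micrococcus had 0, as did all of its shuffles. The runs held 102 of 424 called genes in Herbaspirillum and 181 of 1246 in Pseudomonas. The counts of Herbaspirillum and Pseudomonas are consistent with co-transcribed genes responding together, while annotation of transcripts was not used here.

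The hypothesis that genes of the same name respond alike was tested over 910 names shared by Herbaspirillum and Pseudomonas. Names with several copies in either strain, such as fhuA and fecR in Pseudomonas, were left out. The Spearman correlation was −0.0248 (−0.09 to 0.04), across genes that are not independent replicates, which argues against a general likeness in rank. The Pearson r was 0.18. This pair was 1 of 6 strain pairs computed, and rho of the other pairs ran from −0.0011 to 0.13. The interval of rho lay above 0 only for Herbaspirillum with Micrococcus (0.10, 0.0072 to 0.20). Of 25 names changed in both Herbaspirillum and Pseudomonas, 16 went the same way. Of these, 7 were lower in both, bfrD, bolA, efeU, mbtH, pigA, pvdA and yojI, where independent lists would share 0.879. Another 9 were higher in both, including fumA, cysH, nuoE and gltB, where independent lists would share 4.54. Of the names lower in both, pvdA, mbtH and yojI lay in the same region of Herbaspirillum, so they are not independent. Among single-copy names, a shared response may therefore be limited to a small set of genes.

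In Micrococcus, folds of neighbouring genes were less alike than in Herbaspirillum and Pseudomonas. Low read counts are argued against, because with at least 1000 reads per gene r was 0.25 (0.13 to 0.38), below the 0.93 and 0.94 of those strains at that depth. Scatter between both libraries beyond counting stays open. The spread of folds of deeply read genes was 6.66 times that from counting. This was the smallest ratio of the 4 strains, with 14.3 in Herbaspirillum, 18.6 in Pseudomonas and 13.6 in Pantoea. A true response would give such a spread too, so scatter and response cannot be told apart without replicates. A smaller response in this strain might also lower r, and was not tested.

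In Herbaspirillum, the copper resistance genes copA_1, copB, copC and copD were higher with FeCl3. The lowest of their log2 folds over 3 scalings was 2.60, but the other scalings moved the genes of this strain by at most 0.04, too little to test scaling as the cause. Copper carried in with the FeCl3 could raise copper genes in every strain. The lowest strain median of copper genes was 0.51, in Pseudomonas, just above the bound of 0.5 set earlier, but its interval ran from −2.46 to 2.53, and 3 of its 7 copper genes were higher and 2 lower. Copper carried in and a response to iron itself cannot be told apart here, since the metal content of the media is not given in the sources used here and the copper genes are few.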
